A study of Rattus norvegicus with 8 samples.

How the data were processed

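RNA was measured in 8 tissue samples of adult male Sprague-Dawley rats, 1 PFC and 1 hippocampus library for each of 4 treatments. Per the labels' protocols, tissue was taken in week 7 from 1 unstressed and 2 stressed rats, RNA was purified from about 30 mg of tissue with a column kit, and libraries were sequenced on an Illumina HiSeq instrument. Drugs were injected intraperitoneally each day in the last 3 weeks of the stress protocol, per the series design. The labels give 2 doses for MGO, 5 mM/kg/day in the design and 100 mM/kg in the protocol, and 10 mg/kg/day for luteolin. The protocol does not mention a luteolin rat. The submitters' processing notes name FastQC 0.11.5, HISAT2 2.0.4, StringTie 1.2.4 and the build Rnor_6.0 (rn6), with no role or setting. The annotation release and any filters are not given in the sources used here.

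The deposited table holds 1 value per gene and library, taken here as FPKM computed by the authors. The unit is stated neither in the header nor in the labels. It was inferred from the named tools and from the values, which are not whole numbers and sum to different totals per library, well under those of a unit that sums to the same total. All 8 value columns were matched to samples by title and used. The table gives Ensembl IDs without symbols or coordinates. The symbol table used here, of 47357 genes, matched 0 of the 31185 IDs, so genes are named by ID, no coordinates are given, and the 33 gene lists and the genes named in advance were not evaluated. Values of low genes depend on how StringTie-type quantification divides reads between overlapping or similar gene models, and 229 of the 12155 genes with a mean of at least 1 FPKM were listed at 0 in at least 1 library. A gene at 0 is therefore described as listed at 0, with no fold.

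Low values below 0.2 FPKM of the same gene in a pair of libraries stand in ratios that pile up at 1 constant, the ratio of what a read is worth. This gave relative depths, with the control PFC library as 1, of 0.85, 0.917 and 1.23 for CMS + saline, CMS + MGO and CMS + luteolin in PFC. The values were 1.16, 1.02, 1.05 and 1.34 for control, CMS + saline, CMS + MGO and CMS + luteolin in hippocampus. Constants from any 3 libraries matched within 0.025 on the log2 scale. Reads per gene were not recovered, so no counting interval is given and depth limits only the low genes in a way that could not be quantified.

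Values were analysed as log2(FPKM + 1) over the 12155 genes with a mean of at least 1 FPKM over the 8 libraries. This scale understates the differences of low genes. PFC and hippocampus were compared with limma 3.58.1 in R 4.3.3 (two-sided, trend, treatment as a block, 3 residual degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05. The pairing comes from the protocol, which says that both tissues were taken from each rat it names. It names no luteolin rat, so whether the CMS + luteolin libraries come from the same rat is not stated, and they were paired by treatment. Across genes, the deviations from the tissue means of the PFC and hippocampus libraries of a treatment correlated with r = 0.12 for control, 0.175 for CMS + saline, 0.0458 for CMS + MGO and 0.114 for CMS + luteolin. With 1 library per tissue and treatment, p-values measure how the difference between PFC and hippocampus varied from treatment to treatment. Each gene's variance was moderated towards the trend over all genes, so SEs and p-values draw in part on other genes. On simulated data for this comparison over 12155 genes, limma recovered 64% of 100 genes changed by 1 and 86% of 100 genes changed by 2 on the log2 scale, with 8 false calls and 0 wrong signs.

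Treatments were compared by counting genes with an absolute difference of at least 1 in log2(FPKM + 1), called 2-fold here, with no test. The counting steps were tested on simulated data with changes well past the threshold, which checks the code and not the spread between libraries. Overlaps between tissues were set beside n1 × n2 / N. Overlaps between drugs were set beside the mean of 100 simulations of unchanged libraries that share a control, with each gene's SD over the 4 libraries of the tissue. Counts of genes that moved back were set beside all other assignments of the libraries, of which 12 are distinct because swapping the ends changes nothing. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for these steps.

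The rule for named genes, fixed before the data were examined, took genes with a symbol: the 8 largest rises and falls per treatment comparison and tissue, the 8 genes changed the same way in both tissues with the largest smaller-of-both change, the 10 largest differences each way between tissues with the same direction in all 4 pairs, members of the gene lists, and 12 fixed genes. With no symbols, its rankings were applied to IDs, limited to 2 per direction, for the tissue comparison and for genes changed the same way in both tissues. The alternatives tried were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median-ratio size factors, a 1.5-fold threshold, limma without the block or the trend, and leaving out each pair. After seeing the data, genes above 0 in all 8 libraries and genes within 2-fold in the other tissue were added.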

Results

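The series holds RNA-seq profiles of the prefrontal cortex (PFC) and the hippocampus of adult male Sprague-Dawley rats, an outbred laboratory strain. Its title concerns methylglyoxal (MGO), a reactive dicarbonyl formed mainly as a by-product of glycolysis, and its modification of TrkB, the receptor of brain-derived neurotrophic factor, under chronic stress. Each tissue was profiled under 4 treatments: an unstressed control given saline, and rats under the chronic stress protocol (CMS in the labels) given saline, MGO or luteolin, a plant flavonoid. This makes 8 libraries and 8 groups with 1 library each, so a difference between treatments has no replicate check and no p-value is given for it. The table lists 31185 Ensembl gene IDs, of which 11018 were at 0 in all 8 libraries and 12155 had a mean of at least 1 FPKM (fragments per kilobase of gene model, scaled to the mapped fragments of the library). The sums of FPKM ran from 300281 in the CMS + luteolin hippocampus library to 352740 in the CMS + saline PFC library. Between 11619 and 12028 genes per library were at 1 FPKM or above. Absolute depth is unknown. The steps between low values gave relative depths from 0.85 in the CMS + saline PFC library to 1.34 in the CMS + luteolin hippocampus library, with the control PFC library set to 1. The IDs were not paired with gene symbols here, so genes are given by ID and at most 2 per direction and comparison are named.

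PFC and hippocampus were compared over the 4 libraries of each tissue. Of 12155 genes, 1937 differed (limma, adjusted p under 0.05), with 984 higher in PFC and 953 higher in hippocampus. The balance turned under other settings, for example to 1144 and 1247 without the treatment block. All 1937 differed in the same direction in the 4 pairs of libraries of the same treatment. The genes were called by a test on these same pairs, so this is no separate check. At least a 2-fold difference on the log2(FPKM + 1) scale was found for 535 of them, 287 higher in PFC and 248 higher in hippocampus, and at least a 4-fold difference for 38 and 41. ENSRNOG00000026953 averaged 26.6 ± 5.08 FPKM in PFC and 1.27 ± 0.398 FPKM in hippocampus (SD, n = 4), a log2 difference of 3.60 (SE 0.20, limma adjusted p = 0.00359). ENSRNOG00000015155 averaged 66.6 ± 21.1 FPKM in PFC and 5.52 ± 1.73 FPKM in hippocampus (SD, n = 4), a log2 difference of 3.36 (SE 0.27, limma adjusted p = 0.00567). In the other direction, ENSRNOG00000004179 averaged 29.5 ± 2.5 FPKM in hippocampus and 0.176 ± 0.156 FPKM in PFC (SD, n = 4), a log2 difference of -4.70 (SE 0.10, limma adjusted p = 0.0013). ENSRNOG00000057703 averaged 73.7 ± 59.1 FPKM in hippocampus and 1.73 ± 0.464 FPKM in PFC (SD, n = 4), with 162 FPKM in the CMS + luteolin hippocampus library and 42.6 to 45.7 FPKM in the other 3 hippocampus libraries. Its log2 difference was -4.53 (SE 0.39, limma adjusted p = 0.00656). The libraries of a tissue came from different treatments, so the SDs include treatment. The block removes what both libraries of a treatment share. The SEs and p-values therefore rest on how the difference between tissues varied from treatment to treatment. In limma, each gene's variance was also moderated towards a trend over all genes. The count of differing genes was 243 without the control pair, 499 without the CMS + saline pair, 623 without the CMS + MGO pair, 838 without the CMS + luteolin pair and 792 with no filter on low values.

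**Figure D1:**
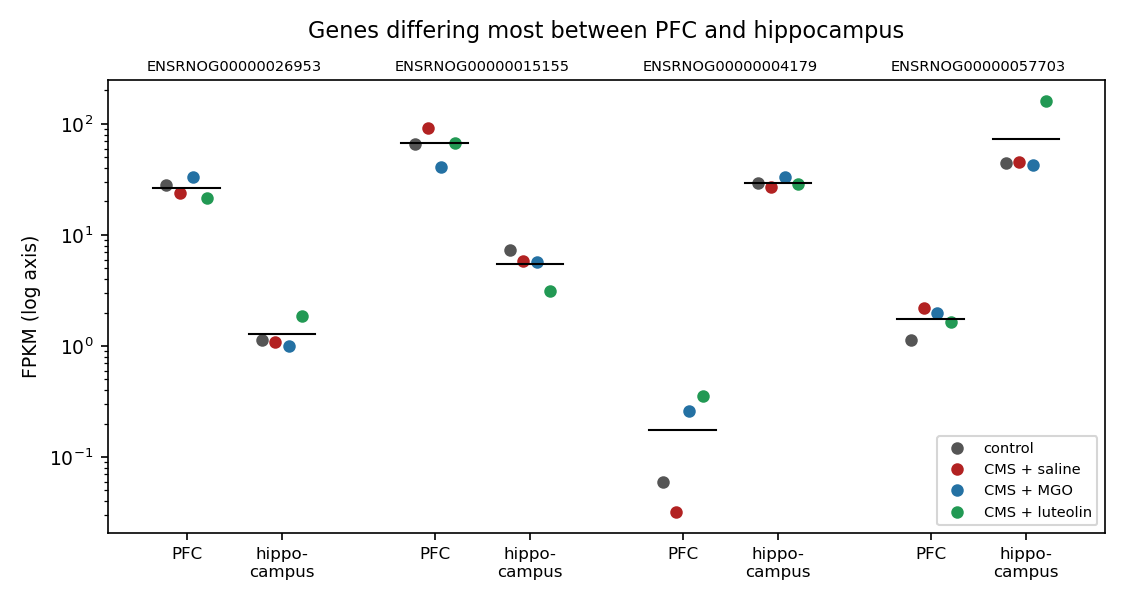
FPKM in each library (log axis) of the 2 genes with the largest difference towards PFC and the 2 with the largest difference towards hippocampus, with points coloured by treatment and a line at the mean of the 4 libraries of a tissue. ENSRNOG00000004179 averaged 29.5 FPKM in hippocampus and 0.176 FPKM in PFC.

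The effect of stress was asked by setting the CMS + saline library against the control library of the same tissue. In PFC, 830 genes (6.83% of 12155) differed at least 2-fold, 476 higher and 354 lower under stress. In hippocampus, 688 genes (5.66%) did, 385 higher and 303 lower. The genes that differed most in the same direction in both tissues went between very low and high values. ENSRNOG00000055319 was at 0.318 FPKM in control PFC and 264 FPKM in CMS + saline PFC, and at 0.72 and 293 FPKM in the corresponding hippocampus libraries. ENSRNOG00000001057 was at 3.43 and 1008 FPKM in PFC and at 1.48 and 313 FPKM in hippocampus. In the other direction, ENSRNOG00000055068 was at 129 FPKM in control PFC and 169 FPKM in control hippocampus and was listed at 0 in both CMS + saline libraries. ENSRNOG00000048980 was at 91.7 and 154 FPKM in the control libraries and was likewise listed at 0 in both. Each of these 4 genes also took both high and low values among the libraries of the drug-treated rats: ENSRNOG00000055068 was at 132 FPKM in CMS + luteolin PFC and listed at 0 in CMS + luteolin hippocampus. The CMS + saline libraries carry another code in their descriptions than the other 6, so stress, rat and this code cannot be told apart. The same difference in code lies between either drug and CMS + saline.

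MGO under stress was set against saline under stress. In PFC, 791 genes (6.51%) differed at least 2-fold, 403 higher and 388 lower with MGO. The balance between higher and lower turned with the scaling, to 368 higher and 430 lower with median-ratio size factors. It leaned further towards higher with a pseudocount of 0.1 (630 higher and 493 lower) and at 1.5-fold (1048 and 815). In hippocampus, 731 genes (6.01%) did, 360 higher and 371 lower. ENSRNOG00000014215 was at 27 FPKM in CMS + MGO PFC and listed at 0 in CMS + saline PFC, and at 26.7 against 0.0738 FPKM in hippocampus. ENSRNOG00000018471 was at 20.6 FPKM in PFC and 23.5 FPKM in hippocampus with MGO and listed at 0 in the control and CMS + saline libraries of both tissues. With luteolin it was at 23.3 FPKM in PFC and 8.83 FPKM in hippocampus. In the other direction, ENSRNOG00000055319 was at 0.468 FPKM in PFC and 0.853 FPKM in hippocampus with MGO. ENSRNOG00000043300 was at 149 FPKM in CMS + saline PFC and 0.846 FPKM in CMS + MGO PFC, and at 125 and 2.17 FPKM in hippocampus. It was also low in control, at 1.63 FPKM in PFC and 0.484 FPKM in hippocampus. With luteolin it was at 125 FPKM in PFC and 75.1 FPKM in hippocampus. Against the control, within the same description code, 834 genes differed at least 2-fold in PFC, 471 higher and 363 lower with MGO, and 690 did in hippocampus, 371 higher and 319 lower.

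Luteolin under stress was set against the same CMS + saline libraries. In PFC, 792 genes (6.52%) differed at least 2-fold, 336 higher and 456 lower with luteolin. In hippocampus, 914 genes (7.52%) did, 417 higher and 497 lower. At 1.5-fold the hippocampus counts were 1263 higher and 1262 lower, and the CMS + luteolin hippocampus library was the one farthest from the others of its tissue, with robust SDs of the log2 differences of 0.41 to 0.44 against 0.19 to 0.21. ENSRNOG00000042556 was at 32.3 FPKM in CMS + luteolin PFC and 43.7 FPKM in CMS + luteolin hippocampus and listed at 0 in both CMS + saline libraries, and it was at 32.4 FPKM in control PFC and listed at 0 in control hippocampus. ENSRNOG00000014215, named above for MGO, was at 19.4 FPKM in PFC and 28 FPKM in hippocampus with luteolin. In the other direction, ENSRNOG00000001057 was at 3.89 FPKM in PFC and 2.04 FPKM in hippocampus with luteolin. ENSRNOG00000007830 was at 70.1 FPKM in CMS + saline PFC and 39.7 FPKM in CMS + saline hippocampus and listed at 0 in both luteolin libraries. It was also low with MGO, at 1.26 FPKM in PFC and listed at 0 in hippocampus. In the control libraries it was at 79.8 FPKM in PFC and 32.3 FPKM in hippocampus. Against the control, 766 genes differed at least 2-fold in PFC, 388 higher and 378 lower with luteolin (376 higher and 392 lower with median-ratio size factors), and 804 did in hippocampus, 443 higher and 361 lower (402 and 395 with median-ratio size factors).

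**Figure D2:**
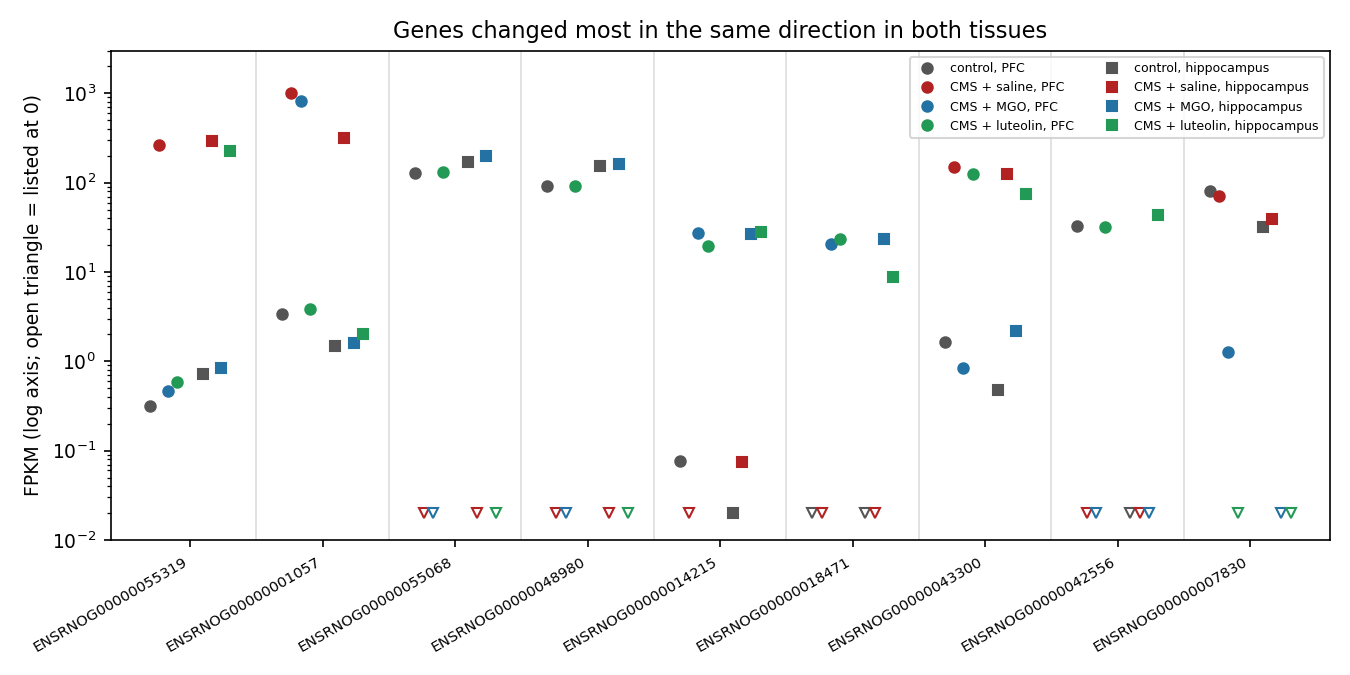
FPKM in each of the 8 libraries (log axis) of the genes that differed most in the same direction in both tissues under stress, MGO or luteolin, with circles for PFC, squares for hippocampus, colours for treatments and open triangles for values listed at 0 (a value above 0 but below 0.02 FPKM is drawn at 0.02). ENSRNOG00000055068 and ENSRNOG00000048980 were listed at 0 in the same 4 libraries.

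No pair of PFC libraries stood apart in the number of differing genes: the 6 pairs of the 4 PFC libraries gave 766 to 834 genes. The 6 hippocampus pairs gave 688 to 986, and the 3 pairs with the CMS + luteolin library gave the 3 highest counts (804, 914 and 986). The robust SDs given above for hippocampus are those of these 3 pairs and of the other 3. In PFC the robust SD was 0.19 between CMS + luteolin and control and 0.27 to 0.33 in the other 5 pairs.

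**Figure D3:**
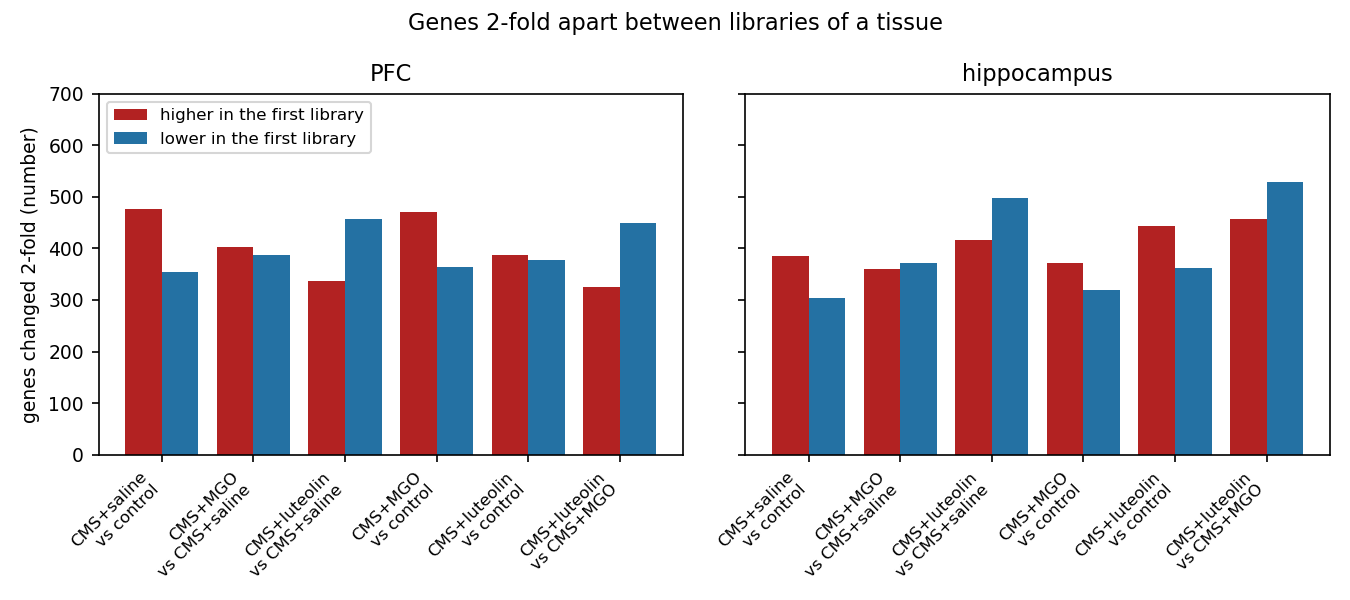
Number of genes with at least a 2-fold difference (y axis) in each pair of libraries of PFC (left) and hippocampus (right), with red bars for genes higher and blue bars for genes lower in the library named first. The total per pair ran from 766 to 834 in PFC and from 688 to 986 in hippocampus.

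Genes that differed under stress and moved back with a drug were counted as those with at least a 2-fold difference between CMS + saline and control and at least a 2-fold difference the other way between the drug and CMS + saline. In PFC, 326 of 830 genes (39.3%) moved back with MGO and 389 (46.9%) with luteolin. In hippocampus, 329 of 688 genes (47.8%) moved back with MGO and 314 (45.6%) with luteolin. Both differences contain the CMS + saline library, so such counts arise whenever a library differs from the others. The control and drug libraries share a description code that CMS + saline does not carry. A difference tied to this code would therefore be counted as moving back with either drug, and the design does not separate the code from treatment. The 12 distinct ways of giving the 4 libraries of a tissue these 3 roles serve as the background. For MGO in PFC, 8 of the 11 other assignments gave as many genes, with a range of 306 to 389. For luteolin in PFC, none of the 11 others did, the highest being 378. The 12 assignments are too few for a share under 0.05, and 4 such counts were ranked. With CMS + MGO in place of CMS + saline between the same ends, control and CMS + luteolin, 374 genes moved back. These ends were the PFC pair with the lowest robust SD (0.19), so the count for luteolin is not read as a reversal of stress. In hippocampus, 4 of 11 gave as many as MGO and 7 of 11 as many as luteolin, with a range of 269 to 452.

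MGO and luteolin were also compared through their differences from the shared CMS + saline library. Across genes, which are not independent replicates, these differences correlated with r = 0.523 in PFC, and simulated unchanged libraries gave 0.502 from the shared library alone. The covariance was 0.223 against a simulated 0.208. In hippocampus r was 0.416 against 0.501, and the covariance 0.178 against 0.21. In PFC, 162 genes were at least 2-fold higher and 184 at least 2-fold lower with both drugs, against 163 and 162 in the simulation and 11.1 and 14.6 for independent lists. In hippocampus, 145 genes were higher and 157 lower with both, against 160 and 163 in the simulation and 12.4 and 15.2 for independent lists. The simulation gave the 4 libraries of a tissue the same spread, a setting that fixes its r in advance. Its covariance and counts follow from each gene's SD over these same 4 libraries, which includes any drug difference. They are therefore no separate comparison. The CMS + luteolin hippocampus library was farther from the others. In PFC the robust SD was 0.19 between CMS + luteolin and control and 0.29 to 0.33 in the pairs with CMS + saline. The simulated values are therefore only a rough reference in both tissues. With 1 CMS + saline library per tissue, the shared library could not be divided to repeat the comparison. Its description code also differs from that of both drugs, so a difference tied to the code would appear with both.

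The differences in PFC and hippocampus were then set side by side. Across 12155 genes, the stress differences of the tissues correlated with r = 0.148 (Spearman's rho 0.125). The correlation was 0.0836 (rho 0.152) for MGO against CMS + saline and 0.194 (rho 0.358) for luteolin against CMS + saline. The latter comparison ran the same way in both tissues along the first axis of the libraries around their tissue means, from 0.273 to -0.145 in PFC and from 0.163 to -0.368 in hippocampus. The other comparisons did so too, with stress from -0.11 to 0.273 in PFC and from 0.0425 to 0.163 in hippocampus. MGO against CMS + saline hardly moved in hippocampus (0.163 to 0.162). The axis was drawn from these same 8 libraries, so it is no separate account of the correlations. The correlation was 0.11 (rho 0.161) for MGO and 0.0928 (rho 0.0972) for luteolin against the control. Under stress, 133 genes differed at least 2-fold in the same direction in both tissues, where independent lists would share 23.9, and 115 differed in opposite directions, where independent lists would share 23.1. For MGO against CMS + saline the counts were 130 in the same direction (23.8 for independent lists) and 100 in opposite directions (23.8). For luteolin against CMS + saline they were 159 (30.2) and 88 (29.4). Genes that differed in a tissue thus tended to differ in the other as well, in either direction. Among genes whose 4 values in the other tissue stayed within 2-fold, an alternative chosen after seeing the data, 308 differed under stress in PFC and 234 in hippocampus.

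**Figure D4:**
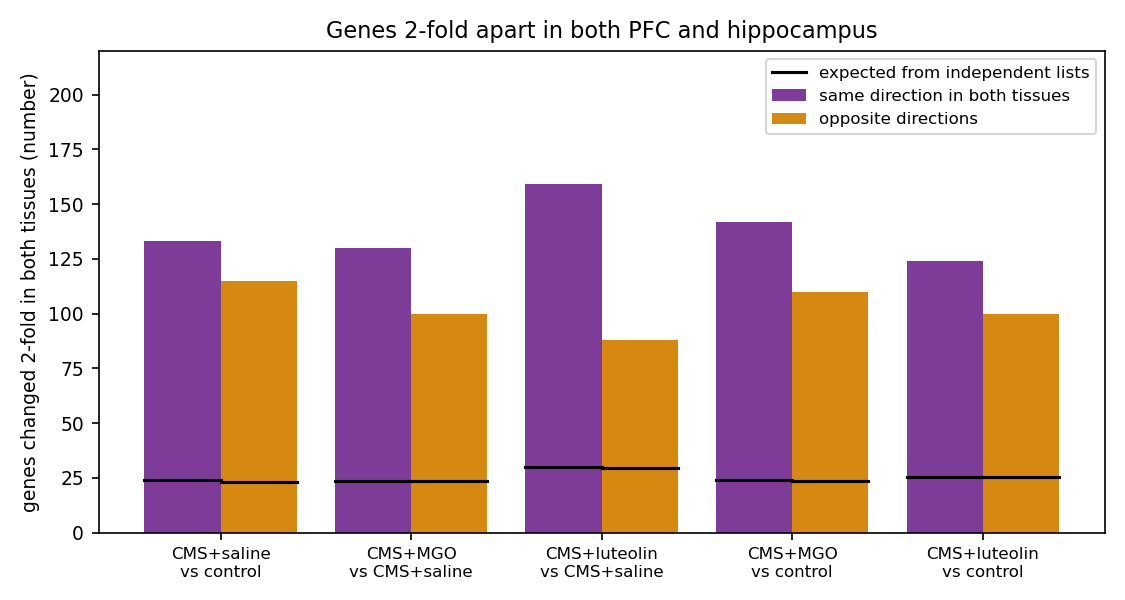
Number of genes with at least a 2-fold difference in both tissues (y axis) for each of 5 comparisons, in the same direction (purple) or in opposite directions (orange), with black lines at the number expected from independent lists. For stress, 133 genes differed in the same direction and 115 in opposite directions, against 23.9 and 23.1.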

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

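Of the tests in this part, those of the library axis and of the splits of the libraries were chosen only after the results were seen. The bounds of 2 kinds of test were also changed after their values were seen: the axis tests first asked only for a rho of 0.7 over all 8 libraries, which the FPKM sum passes and relative depth misses, and the test of the description code first had no allowance for counting error. The CMS + luteolin hippocampus library was far from the other 3 of its tissue in 3 of the 10 groups of 4 values tested in hippocampus, by a rule with which chance flags about 1 in 20; none of the 10 groups in PFC was flagged. It had the lowest sum of FPKM in hippocampus, 300281. It had the highest value of ENSRNOG00000026953 in hippocampus, 1.86 FPKM, and of ENSRNOG00000057703, 162 FPKM.

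Some genes differed at least 2-fold in opposite directions in PFC and hippocampus: 115 for CMS + saline against control, 100 for MGO against CMS + saline, 88 for luteolin against CMS + saline, 110 for MGO against control and 100 for luteolin against control. With 1 library per group, these differences between tissues were not tested.

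With no block, the split of the 8 libraries into PFC and hippocampus gave 2391 differing genes and the highest of the other 34 splits gave 10, so 1 of 35 splits gave as many. Most of these splits do not part the treatment pairs as the design does. Every split other than the real one has both tissues on both sides. The tissue difference then adds to the spread within its sides, with or without the block, and lowers its count. The low counts are therefore no measure of what chance alone would give. With the treatment as a block, 1 of the 8 splits that part every treatment pair gave as many, the real one with 1937 genes, and the highest other gave 1. These 8 splits are too few for a share under 0.05, so the paired design does not settle whether chance can be excluded.

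Some abundant genes switched between a high and a very low value: of 6019 genes reaching 10 FPKM in PFC, 244 (4.05%) were at least 8-fold lower in another PFC library. In hippocampus 239 of 6236 did, and 132 genes switched in both tissues, where independent lists would share 6.19 among the 5527 genes reaching 10 FPKM in both (186 of these switched in PFC and 184 in hippocampus). Counting noise is argued against, since the share of such genes at 50 FPKM and above was 0.98 times that at 10 to 50 FPKM or more in either tissue, and so is a failed library, since at most 29.6% of the lowest values of a tissue fell in any library. Reads passing between 2 of these 132 genes in the quantification are argued against as the main source, since 53 pairs had complementary high and low libraries and 1000 shuffles gave a median of 55 and a highest value of 78; passing to other genes was not tested. A difference between rats or treatments, which the design does not separate, may account for part. Over the 132 genes, deviations of the same treatment correlated with r = 0.198 (0.347 for control, 0.243 for CMS + saline, 0.0563 for MGO and 0.141 for luteolin). This was above all 9 unmatched pairings (highest -0.0062, values that centring on the tissue means pushes below 0). Of 1000 shuffles of each gene's hippocampus libraries, 2 reached it. These shuffles moved each gene on its own. Genes are not independent replicates, so the 2 of 1000 does not serve as a p-value.

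Within tissues, a first axis held 23.8% of the variance of the libraries around their tissue means, with CMS + saline PFC at 0.273 and CMS + luteolin hippocampus at -0.368 as its ends. Scored from the less abundant genes, it went with the FPKM sum of the more abundant genes, a sign that a different share of reads on short gene models might produce (Spearman's rho 0.833, exact permutation p = 0.0154, adjusted 0.0308; Pearson's r 0.916, p = 0.00258, adjusted 0.00516; n = 8; r 0.718 without the 2 farthest libraries). Within PFC and hippocampus rho was 0.4 and 0.2. With relative depth rho was -0.595 (exact permutation p = 0.132, adjusted 0.132, n = 8), and -0.8 in each tissue. Pearson's r was -0.722 (exact permutation p = 0.0482, adjusted 0.0482), and -0.151 without the 2 libraries farthest in depth. Those were the CMS + luteolin libraries (1.23 in PFC and 1.34 in hippocampus). The r without them pools depths that were not centred within tissues, so it does not settle whether the relation rests on these libraries. The permutations for both relations exchanged libraries across tissues, while the scores are centred within each tissue and the sums and depths are not. Their p-values therefore do not cover the order within a tissue. These 2 relations were the ones computed, 4 libraries per tissue do not decide between them, and a treatment difference stays open as untested.

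Both CMS + saline libraries carry their own description code, so a batch could have set them apart in the same genes of both tissues. The number of genes that set both libraries of a treatment at least 2-fold apart from the other 3 of their tissue, in the same direction, was 15 for CMS + saline, 14 for control, 13 for MGO and 13 for luteolin, with 12 of the 15 higher in CMS + saline and 6, 6 and 7 higher in the other 3. Counts this small (95% Poisson interval 8.4 to 24.7 for the 15) do not settle it, and code and treatment cannot be told apart. Over genes that switched in neither tissue, the deviations of the 2 tissues correlated with r = 0.165 for CMS + saline, 0.128 for luteolin, 0.0261 for MGO and 0.0129 for control.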

How the results depend on the processing

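Of 121 alternative values for 20 counts and correlations, 78 stayed within 1.5 times the reported count or within the 95% interval of the correlation across genes, and no correlation changed sign. That interval takes genes as independent replicates, which they are not, so it only serves to sort the correlations. Median-ratio size factors left all 20 counts and correlations within these bounds and moved the share of higher genes by at most 4.83 percentage points. They still turned the balance of higher and lower genes in PFC for MGO against CMS + saline (403 and 388 to 368 and 430) and luteolin against control (388 and 378 to 376 and 392). The balance also turned for the tissues (984 higher in PFC and 953 in hippocampus) with no filter (388 and 404), a mean of at least 5 FPKM (620 and 748), no block (1144 and 1247) and without the CMS + MGO pair (289 and 334), and in hippocampus for luteolin against CMS + saline at 1.5-fold (1263 and 1262) and for MGO against CMS + saline among genes within 2-fold in the other tissue (138 and 132). Genes differing between tissues numbered 1937, and 792 with no filter on low values. Leaving out a pair gave 243 to 838, with fewer libraries. Without the treatment block (the pairing of libraries) 2391 genes differed, 1775 of them shared, and other settings gave 1368 to 2022. No named tissue gene lost its call or its direction under any of these. A mean of at least 5 FPKM, which tests fewer genes, gave 553, 518, 503 and 544 in PFC for stress, MGO and luteolin against CMS + saline and MGO against control, and 451 and 449 in hippocampus for stress and MGO against control. It gave 217 (MGO) and 244 (luteolin) genes moved back in PFC and 217 (MGO) in hippocampus. A 1.5-fold threshold, which passes more genes, gave 1735, 1863, 1720, 1595 and 1334 in PFC for stress, MGO and luteolin against CMS + saline and MGO and luteolin against control, and 1280, 1314, 2525, 1265 and 2289 in hippocampus. It gave 756 (MGO) and 871 (luteolin) moved back in PFC and 583 and 621 in hippocampus. Chosen after seeing the data, genes within 2-fold in the other tissue gave, in the same order, 308, 337, 318, 339 and 304 in PFC and 234, 270, 412, 248 and 361 in hippocampus, since they leave out genes that vary in both. The correlation between tissues was 0.129 for stress and 0.168 for luteolin against CMS + saline with a pseudocount of 0.1, 0.187 for stress with a mean of at least 5 FPKM, and, among genes above 0 in all 8 libraries (added after seeing the data), 0.106 for MGO against CMS + saline and 0.0681 for MGO against control; the cause was not tested. Alternatives for gene lists and genes named in advance were not run, since 0 IDs matched a symbol, and a count-based tool was not run, since the values are not counts. Depth limits low genes, to an extent that the values do not give.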

Other observations

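Of the genes at least 2-fold apart, 14.7% to 20.6% per pair of libraries were genes that reached 10 FPKM in the tissue and were at least 8-fold lower in another of its libraries. Over 4 libraries, 85.3% of genes stayed within 2-fold in PFC and 84.6% in hippocampus. ENSRNOG00000055068 and ENSRNOG00000048980 were at 91.4 to 200 FPKM in 4 libraries (both control libraries, CMS + luteolin PFC and CMS + MGO hippocampus) and listed at 0 in the other 4. Such matches were no more frequent than in shuffles. Among the 132 genes that switched in both tissues, 51 pairs had identical high and low libraries, and 1000 shuffles gave a median of 55. Libraries of the same tissue correlated with r = 0.918 to 0.947 across genes. Libraries of the same treatment but other tissue correlated with r = 0.888 to 0.921, and those differing in both with r = 0.879 to 0.911.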
